A study of Brassica napus with 12 samples.

How the data were processed

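Leaf RNA of 12 Brassica napus samples was sequenced, 2 in each of 6 groups formed by treatment label (S.s., the initials of Sclerotinia sclerotiorum, the stem rot fungus the series title names, or no S.s.) and time (3, 6 or 12 h). Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and made into Illumina libraries. The submitters' processing notes name fastp, HISAT2, RSEM and DESeq2, with no versions. The genome build and the annotation are not given in the sources used here, so no coordinates are printed, and chromosomes are those in the gene identifiers.

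The values deposited by the authors are TPM, with 1 column per library, each adding up to 1000000 within rounding to 2 decimals over 113042 gene models. Of these, 44452 have identifiers of the A subgenome, 56055 of the C subgenome, 533 are unplaced and 12002 are loci assembled outside the named gene models. The deposited table also holds the length of each gene model and its closest SwissProt protein (75616 gene models) and Arabidopsis gene (65479), from which gene names were taken. A further 12 columns of single libraries and 13 of group means were not used. TPM removes depth and sets every library to the same total, so a rise of some transcripts lowers the values of all others, and an exact 0 may be a failed estimate. The spacing of the lowest values against gene length gave an approximate depth of 17.7 to 21.5 times 1000000 reads per library.

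The planned test was one for counts, and the plan named limma on log2 values in case only normalized values were given, which was the case. Log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 with a variance trend, as 6 group means over all 12 libraries, which share 1 estimate of the spread (6 residual and a median of 3 prior degrees of freedom). Gene models with a mean of at least 1 TPM over the 12 libraries were tested (52287). The 60755 left out held up to 0.99% of TPM in a library. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were S.s. against no S.s. at each time, the differences of these effects between times, and the changes with time without S.s. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

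The groups, tests, gene lists and rule for named genes were fixed before the data were examined. The rule names every copy of WRKY40 and of WRKY18, WRKY60 and WRKY33, the 5 largest rises and falls per time among called genes with a name, sufficient expression and both S.s. libraries beyond both others, up to 2 called members per list and time, and the largest differences between times. Where a list had no called member, the rule names its member with the highest expression, and not all of the genes it allows are printed. Of 25 lists, 20 were matched by symbol and 5 by the protein description (jasmonate signalling, heat shock, senescence, all WRKY and ribosomal proteins), after 11 SwissProt entries that share a symbol with another gene were left out. Lists with at least 5 members were tested with camera of limma at a preset correlation between genes of 0.01, with an estimated correlation and the fry test as alternatives.

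The fit was tested on simulated data with 52287 genes and changes at 12 h only. Of 100 genes with a log2 fold change of 1, 11 were called, and of 100 with 2, 81 were called, with median estimates of 0.98 and 2.05. Among unchanged genes 5 were called at 12 h, and 0 at 3 h and at 6 h. In the list test, with 50 genes per list, the 1 changed list was called and 0 of 20 unchanged lists were. The simulation leaves out covariation between genes. It also changed far fewer genes than the 23623 that passed at 12 h in the data. With fewer changed genes the adjusted p is stricter, so the shares called do not describe the 12 h test of the data.

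Alternatives were median-ratio scaling, no filter on low values (80722 genes), a pseudocount of 0.1, a replicate block, a limit of 1 on the absolute log2 fold change, only the 4 libraries of a time, and each library left out. Chosen after the data were seen were the count of genes for which the 2 libraries of 1 group lay beyond all others, the averaging of the 2 libraries without S.s. of each time, a separate spread for the S.s. libraries, and the omission of genes of A01 and C01 or of all chromosomes whose median shifted. The 2 libraries of each group differed by more than the estimated counting noise, by 1.43 to 3.27 times without S.s. and 2.08 to 35.6 times with S.s. They were therefore not merged, which does not show that they came from separate plants.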

Results

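Leaf RNA of Brassica napus (oilseed rape) was sequenced in 12 libraries, all of 1 genotype that the labels call W40. The series design names the W40-OE2 line and infection with Sclerotinia sclerotiorum, the fungus of stem rot, for 3 h, 6 h and 12 h. At each time 2 libraries carried the treatment label S.s. and 2 did not. The labels do not say whether the leaves of the second kind were mock treated or left alone, so they are called libraries without S.s. here. The series title asks about the role of BnaA07.WRKY40 in the defence of rapeseed against this fungus, and the comparison the design allows is S.s. against no S.s. at each time within the W40 genotype. No library of another genotype was analysed here, so an effect of the transgene itself was not measured.

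The table held 113042 gene models, of which 52287 with a mean of at least 1 TPM (transcripts per 1000000) were tested. Depth is not recorded in TPM. The spacing of the lowest values put it at about 17.7 to 21.5 times 1000000 reads per library. Nothing in the labels says that the 2 libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical. Levels are mean TPM ± SD over the 2 libraries of a group (n = 2). Fold changes are log2 differences of TPM + 1, which understates the change of low genes, and are given with the SE and the Benjamini-Hochberg adjusted p of limma. Gene models are named by the identifiers of the table, and A01 to A10 and C01 to C09 are chromosomes read from those identifiers. The 2 subgenomes of this species hold near-identical copies of many genes, and reads shared between copies had to be divided, so the level of a single copy is less certain than that of its gene family.

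WRKY40, a WRKY transcription factor that is rapidly induced by fungal elicitors in Arabidopsis, had 7 tested copies. The copy BnaA07g35260D was the highest of them without S.s., at 44.9 ± 1.15 TPM at 3 h, 137 ± 7.26 TPM at 6 h and 114 ± 5.55 TPM at 12 h. The other copy on A07, BnaA07g20110D, stood at 0.385 ± 0.205, 5.39 ± 0.198 and 0.905 ± 0.304 TPM in the same groups. The labels do not say which of the 2 is the gene of the title. Reads of the transgene and of the plant's own WRKY40 genes cannot be told apart in these values. The levels and changes of the copies below may therefore include both. At 12 h all 7 copies were higher with S.s. BnaA07g20110D rose to 36 ± 13.9 TPM (log2 fold change 4.24, SE 0.64, limma adjusted p = 0.000931) and BnaC02g26030D rose from 20.4 ± 0.658 to 361 ± 155 TPM (4.01, SE 0.50, adjusted p = 0.00034). The assembled locus MSTRG.5775 rose from 3.22 ± 1.25 to 197 ± 122 TPM (5.43, SE 0.61) and BnaAnng23990D from 1.56 ± 0.00707 to 136 ± 68.4 TPM (5.64, SE 0.80). BnaC06g19560D rose from 1.33 ± 0.255 to 42.1 ± 18.6 TPM (4.14, SE 0.61), and BnaC06g40170D from 19 ± 1.22 to 76.1 ± 13.4 TPM (1.94, SE 0.42).

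BnaA07g35260D had the smallest log2 fold change, rising to 194 ± 28.7 TPM at 12 h (0.75, SE 0.27, limma adjusted p = 0.0484), with 214 and 174 TPM in the 2 S.s. libraries against 118 and 110 TPM without S.s. That call was lost with no filter on low values (adjusted p = 0.0755) and in 8 of the 12 fits that left out 1 library. The adjusted p was 0.0727 without either library without S.s. of 3 h, 0.071 without either of 6 h, 0.126 and 0.169 without replicate 1 or 2 of the libraries without S.s. at 12 h, and 0.22 and 0.063 without S.s. replicate 1 or 2 at 12 h. With the 2 libraries without S.s. of each time averaged to 1, the calls of BnaA07g35260D, BnaA07g20110D and BnaC06g40170D at 12 h were lost, at adjusted p of 0.281, 0.0534 and 0.112.

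**Figure D1:**
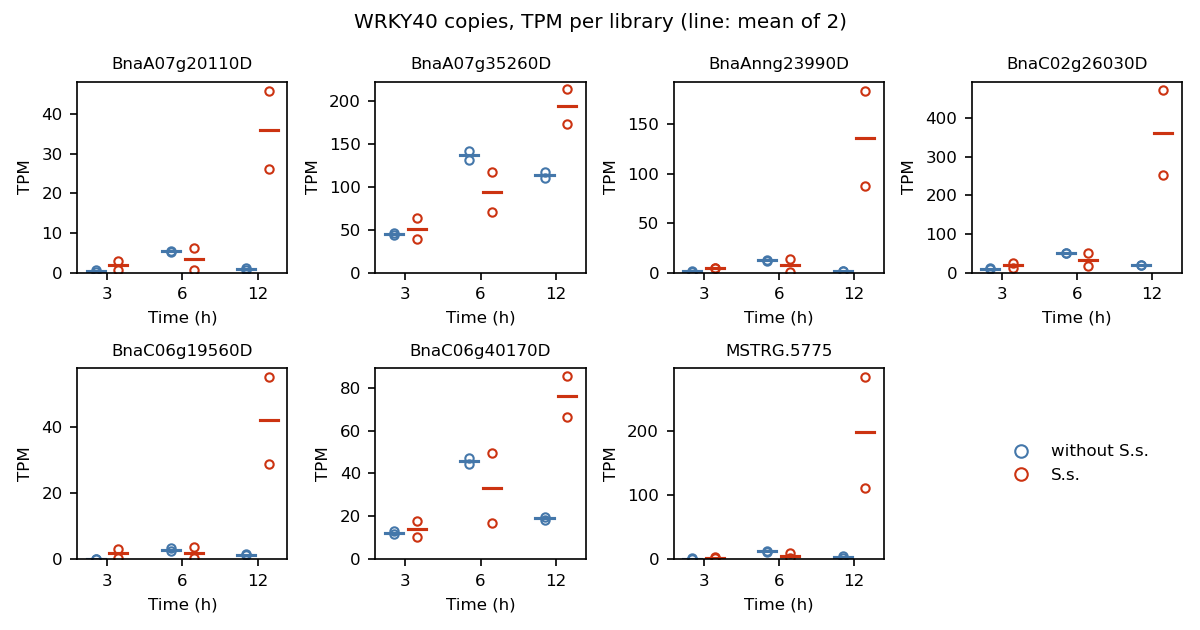
TPM (linear axis, 1 panel per copy with its own scale) of the 7 tested WRKY40 copies against time in hours, with 1 circle per library, blue without S.s. and red with S.s., and a line at the mean of the 2 libraries. Both S.s. libraries of 12 h lie above both libraries without S.s. of 12 h for every copy, and the smallest log2 fold change, 0.75, was that of BnaA07g35260D, from 114 to 194 TPM.

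No copy of WRKY40 passed the test at 3 h or 6 h. The values at 3 h with S.s. were 1.86 ± 1.58 TPM for BnaA07g20110D, 51.2 ± 17.7 for BnaA07g35260D, 4.3 ± 0.0778 for BnaAnng23990D, 18.7 ± 9.3 for BnaC02g26030D, 1.74 ± 1.8 for BnaC06g19560D, 14.2 ± 5.38 for BnaC06g40170D and 2.4 ± 0.368 for MSTRG.5775, with limma adjusted p between 0.288 and 0.889. The 2 S.s. libraries of 6 h lay far apart. BnaC02g26030D had 16.3 TPM in replicate 1 and 50.4 in replicate 2, and BnaAnng23990D had 0.71 and 13.6 TPM, while the libraries without S.s. lay at 49.6 and 51 TPM and at 12 and 12.6 TPM. The means of the 7 copies at 6 h were all lower with S.s., with log2 fold changes of -1.41 to -0.58 and adjusted p between 0.739 and 0.939. For 5 of the 7 that direction rests on S.s. replicate 1, without which 4 copies had log2 fold changes of 0.11 to 0.24 and BnaC02g26030D one of 0.

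WRKY18, which forms dimers with WRKY40, and WRKY33, a regulator of camalexin synthesis, were followed in the same way. At 12 h all 6 tested copies of WRKY18 and all 7 of WRKY33 rose. Among WRKY18 copies, BnaC07g43490D rose from 10.4 ± 1.02 to 136 ± 22.2 TPM (log2 fold change 3.58, SE 0.41, limma adjusted p = 0.000208). BnaAnng32610D reached 82.7 ± 14.1 TPM (2.95), BnaC01g06660D 39.8 ± 26.2 TPM (3.20), BnaC03g67380D 35.1 ± 2.31 TPM (2.45), MSTRG.23140 33.6 ± 7.95 TPM (2.45) and BnaA01g05060D 22.2 ± 11.4 TPM (2.72). Among WRKY33 copies, BnaC03g21360D rose from 21.6 ± 0.7 to 306 ± 114 TPM (3.71, SE 0.45, adjusted p = 0.000279) and BnaA05g34850D from 5.5 ± 0.177 to 232 ± 107 TPM (5.08, SE 0.36, adjusted p = 1.56e-05). The other 5 reached 180 ± 70.2 TPM (BnaCnng66020D, 4.55), 144 ± 58.2 (BnaA04g22040D, 4.56), 134 ± 70.5 (BnaC04g06800D, 5.29), 89 ± 34.8 (BnaA03g17820D, 3.42) and 17.7 ± 8.9 (BnaC07g27590D, 3.52). No copy of either gene passed at 3 h or 6 h. Without S.s. replicate 2 of 3 h, the WRKY18 copies BnaC03g67380D and MSTRG.23140 passed at 3 h, at adjusted p of 0.0208 and 0.00961. The call of MSTRG.23140 at 12 h was lost (adjusted p = 0.0625) with the libraries without S.s. averaged. No gene model of the table was matched to WRKY60. The list called WRKY40 and its partners below therefore holds the tested copies of WRKY40, WRKY18 and WRKY33. Its name does not state that WRKY33 dimerizes with WRKY40.

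At 3 h, 2606 genes rose and 1512 fell with S.s. Pathogenesis-related protein 1 (BnaC03g45470D), a marker of salicylic acid responses, rose from 272 ± 4.39 to 1340 ± 70.8 TPM (log2 fold change 2.30, SE 0.23, limma adjusted p = 0.00168), and the endochitinase CHI (BnaC04g53030D) from 6.44 ± 1.29 to 89.6 ± 15.3 TPM (3.61, SE 0.35, adjusted p = 0.00139). Nitrile-specifier protein NSP5, which acts in glucosinolate breakdown, rose in 2 copies, from 9.75 ± 1.18 to 90 ± 32.3 TPM (BnaA06g30390D, 3.04, SE 0.22) and from 29 ± 1.92 to 111 ± 19.5 TPM (BnaC07g26280D, 1.89, SE 0.15). The 5 named genes with the largest rise all lie on A01. They were PSBQ1 of photosystem II (BnaA01g11190D, 0.07 ± 0 to 118 ± 12.5 TPM), the phloem protein PP2A1 (BnaA01g34970D, 0.105 ± 0.148 to 121 ± 74.4 TPM), phosphoglycerate kinase PGK1 (BnaA01g30320D, 0.58 ± 0.113 to 136 ± 47.9 TPM), the ubiquitin-like UBL5 (BnaA01g24730D, 0.475 ± 0.672 to 141 ± 117 TPM) and the iron superoxide dismutase FSD1 (BnaA01g14450D, 0.54 ± 0.283 to 149 ± 135 TPM). Of the 5 largest falls, RPS27B (BnaC07g49260D), UBP13 (BnaCnng67940D) and SAUR21 (BnaA10g16840D) are listed at 0 in both S.s. libraries. UBP13 is also listed at 0 in both libraries without S.s. of 6 h. RPS27B had 67.9 and 0.08 TPM in the 2 S.s. libraries of 12 h, so values near 0 were not tied to the treatment. XTH6 (BnaA06g24680D), a cell wall enzyme, fell from 56 ± 3.78 to 4.38 ± 2.69 TPM (SE 0.38, adjusted p = 0.00217) and the MADS-box gene AGL19 (BnaC07g37730D) from 19.1 ± 2.64 to 1.19 ± 1.68 TPM.

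The 2 libraries without S.s. of 3 h stood apart from all others, at -107.7 and -108.1 on the second principal component against -35.5 to 91.6. Of the rises at 3 h, 54.8% had both of them below all other 10 libraries, and of the falls 75.6% had both above. Both S.s. libraries of 3 h lay beyond all others for 18% of the rises and 11.2% of the falls. Among all genes tested these shares were 6.5% and 12.4% for the libraries without S.s. and 5.8% and 1.4% for those with S.s. A random order of 12 unrelated libraries gives 1.5%. That reference is too low here, because the 2 libraries of a group lie close together. Called genes were also selected for a difference between the treatments at 3 h. In the 4 libraries without S.s. of 6 h and 12 h, pathogenesis-related protein 1 (BnaC03g45470D) had 1103 to 1289 TPM, CHI (BnaC04g53030D) 57.6 to 87.7 TPM and XTH6 (BnaA06g24680D) 1.7 to 5.28 TPM, while the means with S.s. at 3 h were 1340, 89.6 and 4.38 TPM. Across genes, which are not independent replicates, the effect of S.s. at 3 h had an r of 0.65 with the change from 3 h to 6 h without S.s., which shares these libraries (mean of 0.37 in simulations with no effect).

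The A01 genes stood low in the 2 libraries without S.s. of 3 h. Relative to each gene's median over the libraries, their median log2 level was -0.82 and -0.81 there and between -0.25 and 0.17 in the other 10 libraries. The C01 genes stood high in the same 2 libraries, at 0.30 and 0.31, and so did the A10 genes, at 0.20 and 0.21. In S.s. replicate 1 of 6 h, A10 stood at -0.35 and C05 at 0.21. A01 held 3.4% of the genes tested and 27.2% of the rises at 3 h (710 genes), and C01 held 3.6% of the genes tested and 13.4% of the falls (202 genes). A10 held 3.1% and 5% of the falls (76 genes), LHCB3 (BnaA10g07350D) and SAUR21 (BnaA10g16840D) among them. Among 898 well expressed A01 genes, 28.5% and 29.1% were under 0.1 times their median in these 2 libraries, against 0 to 6.1% in the others. Without the genes of A01 and C01, 2548 genes passed at 3 h (1499 rose, 1049 fell), and 2290 without those of A01, A09, A10, C01 and C05, all chromosomes whose median shifted.

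**Figure D2:**
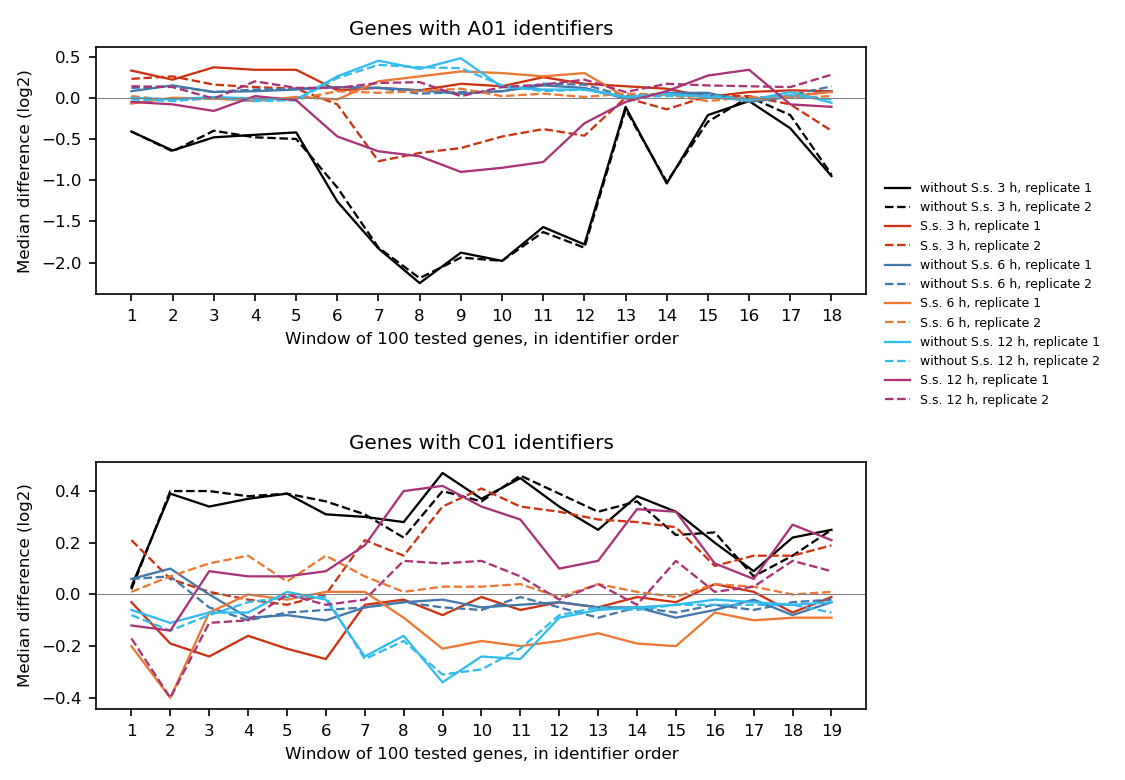
Median log2 level of windows of 100 tested genes in identifier order on A01 (upper panel) and C01 (lower panel), relative to each gene's median over the 12 libraries, with 1 line per library. The 2 libraries without S.s. of 3 h (black) reach -2.25 and -2.19 on A01 and lie above 0 in all windows of C01, and S.s. replicate 2 of 3 h and S.s. replicate 1 of 12 h are lower over part of A01, down to -0.77 and -0.9.

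Counts for the 25 fixed gene lists at 3 h are given with the number of rises on A01 where it was above 0. Of 49 genes of salicylic acid synthesis and signalling 9 rose and 0 fell, 2 of the 9 on A01. They included the receptor NPR4 (BnaA01g10220D, on A01, 1.62 ± 0.191 to 7.16 ± 1.32 TPM) and isochorismate synthase ICS1 (BnaA07g22090D, 4.95 ± 0.0849 to 9.88 ± 1.62 TPM). Of 40 pathogenesis-related genes 7 rose, 0 of them on A01, and 0 fell. Of 192 WRKY genes 20 rose, 2 of them on A01, and 0 fell, among them WRKY65 (BnaA08g18040D, 0.345 ± 0.0212 to 3.22 ± 0.948 TPM) and WRKY25 (BnaC04g41050D, 7 ± 0.304 to 17 ± 3.1 TPM). Glucosinolate synthesis was split, with 7 rises and 3 falls among 42 genes. SUR1 (BnaCnng43090D) rose from 5.53 ± 0.269 to 13.6 ± 2.45 TPM, and CYP83A1 (BnaA04g06630D), of the aliphatic branch, fell from 10.2 ± 0.361 to 2.15 ± 0.636 TPM. Of 13 genes of glucosinolate breakdown 4 rose. Adjusted p values with an estimated correlation between genes were 0.647, 0.129, 0.55, 0.666 and 0.637 for these 5 lists in the order given. For NPR4, ICS1, WRKY65, WRKY25 and SUR1, both libraries without S.s. of 3 h lay beyond all other libraries. For CYP83A1 they did not.

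Among 55 genes of jasmonate signalling 3 rose (1 on A01) and 1 fell on C01. TIFY6B (BnaC05g35610D), a jasmonate signalling repressor, rose from 10.6 ± 0.707 to 31.4 ± 9.64 TPM, while TIFY8 (BnaC01g05900D) fell from 13 ± 0.898 to 5.71 ± 1.2 TPM. Of 50 ethylene genes 4 rose (2 on A01) and 1 fell, and the ethylene receptor ETR2 (BnaCnng68360D) rose from 3.25 ± 0.438 to 16.1 ± 3.3 TPM. Tau class glutathione transferases went both ways, 5 up and 3 down of 35. GSTU22 (BnaC08g35100D) rose from 20 ± 0.276 to 44.3 ± 2.95 TPM and GSTU17 (BnaA06g06160D) fell from 94.6 ± 2.02 to 40.6 ± 8.78 TPM. Of 24 genes of the abscisic acid response 3 rose (1 on A01), with the dehydrin RAB18 (BnaC02g45160D) going from 1.82 ± 0.134 to 20 ± 8.91 TPM. Their adjusted p with an estimated correlation was 0.666, 0.666, 0.653 and 0.666. Photosynthesis genes fell in 9 of 66 cases and rose in 2, 1 of them on A01. LHCB3 (BnaA10g07350D) went from 262 ± 7.83 down to 75.4 ± 1.61 TPM, and LHCA3 (BnaA01g22670D, on A01) from 0.7 ± 0.0849 up to 73.8 ± 51.3 TPM. Of 808 cytosolic ribosomal protein genes 14 rose, 13 of them on A01, and 58 fell, 12 of them on C01, including RPS13B (BnaA07g18810D, 14.4 ± 0.799 to 5.74 ± 1.03 TPM). The cuticle list fell in 4 of 28 (LTPG1, BnaCnng36210D, 64.3 ± 4.69 to 22.2 ± 6.34 TPM) and the phloem companion cell list in 4 of 22 (the sucrose transporter SUC2, BnaC07g13570D, 103 ± 2.68 to 41.3 ± 8.61 TPM). These 4 lists had an adjusted p of 0.666, 0.55, 0.55 and 0.666 with an estimated correlation. Both libraries without S.s. of 3 h lay beyond all other libraries for TIFY6B, TIFY8, GSTU22, GSTU17, RAB18, LHCA3, RPS13B and LTPG1. They did not for ETR2, LHCB3 and SUC2.

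Of the other lists, rises and falls at 3 h were 1 and 0 of 35 for jasmonate synthesis, 2 and 0 of 19 for camalexin, 3 and 0 of 33 for reactive oxygen, 1 and 0 of 49 for phenylpropanoids, 2 and 0 of 45 for pattern recognition, 2 and 1 of 46 for heat shock, 0 and 0 of 26 for guard cells, 6 and 1 of 39 for senescence, 4 and 0 of 28 for the clock, 0 and 1 of 18 for cell division and 1 and 1 of 42 for auxin. The only rises of the jasmonate synthesis and auxin lists lie on A01. So do 1 rise each of the reactive oxygen, pattern recognition and clock lists and 2 of the senescence list. Adjusted over the list alone, the counts were larger for glucosinolate synthesis (16 and 4), tau glutathione transferases (13 and 3), pathogenesis-related proteins (11 and 1), photosynthesis (2 and 16), ribosomal proteins (14 and 69), WRKY genes (23 and 0), ethylene (6 and 1), glucosinolate breakdown (5 and 0), senescence (8 and 2), cuticle (0 and 6), phloem (0 and 5) and cell division (3 and 1), were 1 and 0 for pattern recognition, and were the same for the other 12. With median-ratio scaling, 9 WRKY genes and 3 salicylic acid genes rose. The camera test passed 14 of the 25 lists at 3 h with its preset correlation of 0.01 and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05. Without S.s. replicate 1 of 3 h it passed 6. The median of the glucosinolate breakdown list (-0.01) differed in sign from its mean (0.59) and its test. The auxin list had a median of -0.02, a mean of 0.08 and a downward test that did not pass, and the tests of the phenylpropanoid (median 0.03) and heat shock lists (median 0.02), which also did not pass, pointed down.

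The 3 h counts depended on the libraries without S.s. They were 499 and 564 genes without replicate 1 or 2 of that group, 2540 without either library without S.s. of 6 h, and 2493 and 2490 without replicate 1 or 2 of those of 12 h. Limma called 0 genes with the libraries without S.s. averaged (4815 at an unadjusted p under 0.05, against 12488 here) and 0 with only the 4 libraries of 3 h in the fit (10210 unadjusted), so none of the genes named for 3 h passed there. Of 31 named and called at 3 h, 15 lost their call when 1 library was left out, at adjusted p of 0.0528 to 0.245. Without replicate 1 of the 3 h libraries without S.s. these were LHCA3, GSTU17, ICS1, WRKY65, LHCB3, SAUR21, TIFY8, RAB18, WRKY25, TIFY6B, AGL19, RPS27B, GSTU22, LTPG1 and SUR1, and without replicate 2 the same ones except LTPG1 and SUR1. ICS1 was also lost without S.s. replicate 2 of 3 h (adjusted p = 0.0591), and RPS27B without either S.s. library of 3 h (0.115 and 0.11), without either library of 6 h of both kinds (0.0681 to 0.0817), without those without S.s. of 12 h (0.0829 and 0.083), with median-ratio scaling (0.0627), with no filter on low values (0.0844) and without the genes of A01 and C01 (0.0569).

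At 6 h, 3 genes rose and 6 fell with S.s. NSP5 (BnaC07g26280D), which had risen at 3 h, fell from 47.4 ± 0.933 to 16.5 ± 1.76 TPM (log2 fold change -1.47, SE 0.15, limma adjusted p = 0.027). IGMT1 (BnaC08g19680D), a methyltransferase of indole glucosinolates, fell from 5.91 ± 0.0566 to 1.67 ± 0.283 TPM (-1.38, SE 0.14, adjusted p = 0.027). The receptor kinase gene EMS1 (BnaC09g48450D) fell from 7.96 ± 0.0636 to 0.215 ± 0.0495 TPM, and lay between 0.14 and 0.47 TPM in all 10 libraries other than the 2 without S.s. of 6 h. The 3 genes that rose have no name in the table and are listed at 0 in both libraries without S.s., with 10.8 ± 0.0919 TPM for BnaA03g48730D, 6.64 ± 1.82 for BnaC05g14380D and 15 ± 0.389 for MSTRG.49958 with S.s. MSTRG.49958 is listed at 0 in those 2 libraries alone and had 7 to 25.4 TPM in the other 10, while the other 2 are listed at 0 in all 6 libraries without S.s. These 3 and EMS1 were chosen after their values were seen. Pathogenesis-related protein 1 (BnaC03g45470D), which had risen at 3 h, stood at 1289 and 1255 TPM in the 2 libraries without S.s. and at 1360 ± 304 TPM with S.s. (0.07, SE 0.23, adjusted p = 0.996, and -0.16 without S.s. replicate 1), and CYP83B1 (BnaA08g04520D), of the indole glucosinolate pathway, at 65 ± 3.32 and 36.4 ± 2.98 TPM (-0.82, SE 0.21, adjusted p = 0.375).

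Of the 25 lists, 1 had a called member at 6 h, glucosinolate breakdown with NSP5 among 13 genes (adjusted p = 0.31 with an estimated correlation). Adjusted over the list alone, 0 rose and 13 of 42 glucosinolate synthesis genes fell, 8 of 35 tau glutathione transferases fell, 8 of 192 WRKY genes fell, 5 of 49 salicylic acid genes fell and 1 rose, 3 of 13 glucosinolate breakdown genes fell and 3 of 28 clock genes rose, with 1 fall each for jasmonate synthesis, photosynthesis, phloem and auxin and 0 calls in the other 15. The camera test passed 17 lists, 14 of them downwards. The medians were -0.87 for WRKY40 and its partners, -0.54 for tau glutathione transferases and -0.52 for glucosinolate synthesis, with adjusted p of 0.349, 0.252 and 0.31 with an estimated correlation, under which 0 lists passed (3 unadjusted). Without S.s. replicate 1 of 6 h it passed 10, and the median of WRKY40 and its partners was -0.30, against -1.45 without replicate 2.

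The limma test at 6 h gave 3488 of 52287 genes at an unadjusted p under 0.05. With no effect at all, a share of 0.05 of the genes tested would be expected there. The count of 9 became 4 without either library without S.s. of 3 h, 57 and 53 without S.s. replicate 1 or 2 of 3 h, 18 and 15 without replicate 1 or 2 of the libraries without S.s. of 6 h and 26 without S.s. replicate 2 of 6 h. It was 0 with the libraries without S.s. averaged (942 unadjusted) and 0 with only the 4 libraries of 6 h (4924 unadjusted). All 6 genes named as changed at 6 h lost their call in at least 1 of the 12 fits that left out a library, at adjusted p of 0.0515 to 0.188, NSP5 and IGMT1 without either library without S.s. of 3 h, 6 h or 12 h and without either S.s. library of 6 h, IGMT1 and MSTRG.49958 also without either S.s. library of 12 h. EMS1 and BnaA03g48730D lost it without S.s. replicate 1 of 6 h, EMS1 also without either library without S.s. of 6 h. BnaC05g14380D lost it without either library without S.s. of 3 h or 6 h, without replicate 2 of those of 12 h and without S.s. replicate 1 of 6 h, and MSTRG.49958 without either library of 6 h of both kinds and without either without S.s. of 12 h. A pseudocount of 0.1 ended the calls of BnaC05g14380D and EMS1 (adjusted p of 0.244 and 0.0689), and a separate spread for the S.s. libraries that of MSTRG.49958 (0.0997).

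At 12 h, 8048 genes rose and 15575 fell with S.s., out of 52287 tested. A lectin-like protein (BnaCnng78710D, the product of At3g16530 in Arabidopsis) rose from 0.89 ± 0.495 to 722 ± 257 TPM (log2 fold change 8.56, SE 0.42, limma adjusted p = 3.83e-06). The cytochrome P450 CYP72A15 (BnaC01g36670D) rose from 0.365 ± 0.0919 to 338 ± 132 TPM (7.90, SE 0.29), the ethylene response factor ERF14 (BnaC08g43940D) from 0.18 ± 0.255 to 288 ± 125 TPM (7.88, SE 0.30) and the precursor of the secreted peptide PIP2 (BnaC01g01620D) from 2.01 ± 0.813 to 612 ± 208 TPM (7.65, SE 0.49). A second PIP2 copy (BnaA08g15620D) is listed at 0 without S.s. and had 183 ± 10.6 TPM with S.s. The lipid transfer protein genes LTP4 (BnaC02g10050D, 1100 ± 4.48 to 17.7 ± 10.1 TPM, -5.99, SE 0.77) and LTP3 (BnaA03g09530D, 799 ± 12.6 to 8.3 ± 4.12 TPM, -6.50, SE 0.71) and the dehydrin RAB18 (BnaCnng27850D, 270 ± 0.141 to 3 ± 1.29 TPM, -6.12, SE 0.43) fell most. Their high level was that of the 2 libraries without S.s. of 12 h alone, since all 8 libraries of 3 h and 6 h had 3.23 to 34.2 TPM of LTP4, 2.69 to 24 of LTP3 and 0 to 1.72 of RAB18. Of the falls at 12 h, 26.5% had both libraries without S.s. of 12 h above all other 10 and 65.8% had both S.s. libraries of 12 h below all others. For the rises these shares were 14.1% and 81.2%. Among all genes tested they were 10% and 26.8% in the order of a fall and 3.6% and 14.6% in that of a rise. The 1.5% of a random order of unrelated libraries is too low a reference here as well, for the reasons given for 3 h. Correlations across genes were 0.664 to 0.747 between S.s. and no S.s. at 12 h, against 0.873 to 0.896 at 3 h and 0.931 to 0.947 at 6 h, and 0.904 to 0.963 within groups.

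The median log2 fold change of all genes at 12 h was -0.315 in TPM and -0.021 with median-ratio scaling. The medians of lists at 12 h are therefore given relative to all genes. With that scaling 11410 genes rose and 8510 fell, which is 42.7% falls against 65.9% in TPM. Each list below that passed camera lost that with an estimated correlation, and the adjusted p of that test is given with it.

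At 12 h, of 19 genes of the list for camalexin and indole phytoalexins 17 rose and 0 fell (median 3.82, adjusted p = 0.079 with an estimated correlation). They are called camalexin genes elsewhere for short. The list includes tryptophan pathway genes, and its count does not show that camalexin itself was made. The tryptophan pathway enzyme ASA1 (BnaA10g24820D) went from 3.32 ± 0.898 to 89.5 ± 5.78 TPM (log2 fold change 4.40, SE 0.19, limma adjusted p = 2.54e-06). Of 42 genes of glucosinolate synthesis 33 rose and 2 fell (median 3.55, adjusted p = 0.0732 with an estimated correlation). The C-S lyase SUR1, which serves both aliphatic and indole glucosinolates, rose from 28.5 ± 1.45 to 741 ± 189 TPM (BnaA07g00460D, 4.63, SE 0.20) and from 11.3 ± 0.516 to 303 ± 30 TPM (BnaCnng43090D, 4.63, SE 0.15). Of 13 genes of glucosinolate breakdown 2 rose and 6 fell (median -0.48, adjusted p = 0.468 with an estimated correlation and 0.215 with the preset one), and the NSP5 copy BnaC05g44250D fell from 50.5 ± 0.148 to 12.6 ± 0.191 TPM. The 2 NSP5 copies that had risen at 3 h were the ones that rose, BnaC07g26280D from 86.4 ± 2.81 to 172 ± 9.46 TPM (0.98, SE 0.15, adjusted p = 0.000939) and BnaA06g30390D from 45 ± 2.17 to 73.2 ± 8.44 TPM (0.69, SE 0.22, adjusted p = 0.0338). The latter call was lost without any 1 library of 12 h and without either library without S.s. of 6 h (0.0524 to 0.137), and both with the libraries without S.s. averaged (0.234, and 0.0647 for BnaC07g26280D).

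Of 55 genes of jasmonate signalling, mostly TIFY (JAZ) repressors, 41 rose and 4 fell (median 3.17, adjusted p = 0.152 with an estimated correlation), and TIFY5A (BnaC05g23060D) rose from 0.985 ± 0.233 to 33.2 ± 2.06 TPM. Jasmonate synthesis had 23 rises and 4 falls among 35 (median 1.72, 0.152 as adjusted p of the same test), with allene oxide cyclase AOC2 (BnaC09g52570D) going from 0.995 ± 0.134 to 81.7 ± 17 TPM. Ethylene genes went both ways, 26 up and 17 down of 50 (median 1.43, adjusted p = 0.481). The synthesis gene ACS2 (BnaC05g00530D) rose from 1.27 ± 0.184 to 97.8 ± 38.4 TPM, while EBF2 (BnaA09g04600D), a repressor of ethylene signalling, fell from 63.8 ± 2.03 to 10.1 ± 3.01 TPM. Of 49 salicylic acid genes 26 rose and 3 fell (median 1.06, adjusted p = 0.152), including ICS1 (BnaCnng08300D, 13 ± 0.198 to 115 ± 46 TPM) and WRKY70 (BnaCnng52600D, 13.9 ± 2.3 to 110 ± 20.9 TPM). The abscisic acid response fell in 16 of 24 genes and rose in 0 (median -1.02, adjusted p = 0.262), with the transcription factor ABF3 (BnaC07g44670D) going from 35.6 ± 0.587 to 5.08 ± 0.686 TPM. ABF3 had 6.66 to 12.4 TPM in the 8 libraries of 3 h and 6 h, and without S.s. the list itself rose in 12 of 24 genes from 6 h to 12 h (adjusted p = 0.28 with an estimated correlation). Auxin response genes fell in 22 of 42 cases and rose in 6 (median -0.96, and -0.46 without S.s. replicate 1 of 12 h, adjusted p = 0.535 and 0.063 with the preset correlation). IAA19 (BnaCnng74250D) fell from 46.7 ± 2.23 to 11.7 ± 1.52 TPM and SAUR36 (BnaA03g45460D) rose from 3.94 ± 0.148 to 132 ± 49.6 TPM.

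Among recognition and defence genes, 20 of 20 copies of WRKY40 and its partners rose (median 3.96, adjusted p = 0.152 with an estimated correlation) and of all 192 WRKY genes 104 rose and 29 fell (median 1.42, adjusted p = 0.0851). WRKY75 (BnaC03g05760D) went from 0.815 ± 0.601 to 82.2 ± 4.27 TPM and WRKY6 (BnaA09g13370D) from 3.14 ± 0.127 to 90.6 ± 28 TPM. Of 45 genes of pattern recognition and kinase signalling 30 rose and 2 fell (median 1.84, adjusted p = 0.0994), among them the chitin receptor kinase CERK1 (BnaA05g19600D, 1.9 ± 0.0354 to 25.3 ± 6.89 TPM) and the kinase MPK4 (BnaA03g26950D, 17.3 ± 0.728 to 78.2 ± 22.5 TPM). Tau class glutathione transferases, which conjugate toxic compounds, rose in 27 of 35 cases and fell in 2 (median 2.41, adjusted p = 0.0732), with GSTU11 (BnaCnng49200D) going from 0.495 ± 0.205 to 161 ± 29 TPM. Phenylpropanoid genes rose in 28 of 49 cases and fell in 7 (median 1.38, adjusted p = 0.0732). The lyase PAL2 (BnaC06g14510D) went from 1.65 ± 0.0212 to 57.1 ± 4.81 TPM and the reductase CCR2 (BnaC06g40190D) from 0.61 ± 0.0566 to 116 ± 43 TPM. Pathogenesis-related genes rose in 15 of 40 cases and fell in 4 (median 0.79, adjusted p = 0.0732), including the polygalacturonase inhibitor PGIP1 (BnaA10g24060D, 2.02 ± 1.12 to 57.4 ± 2.21 TPM). Reactive oxygen genes went both ways, 13 up and 9 down of 33 (median 0.27, and 0.44 without replicate 2 of those without S.s., adjusted p = 0.24), and the oxidase RBOHD (BnaA06g30520D) rose from 1.87 ± 0.714 to 66.2 ± 21.9 TPM.

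**Figure D3:**
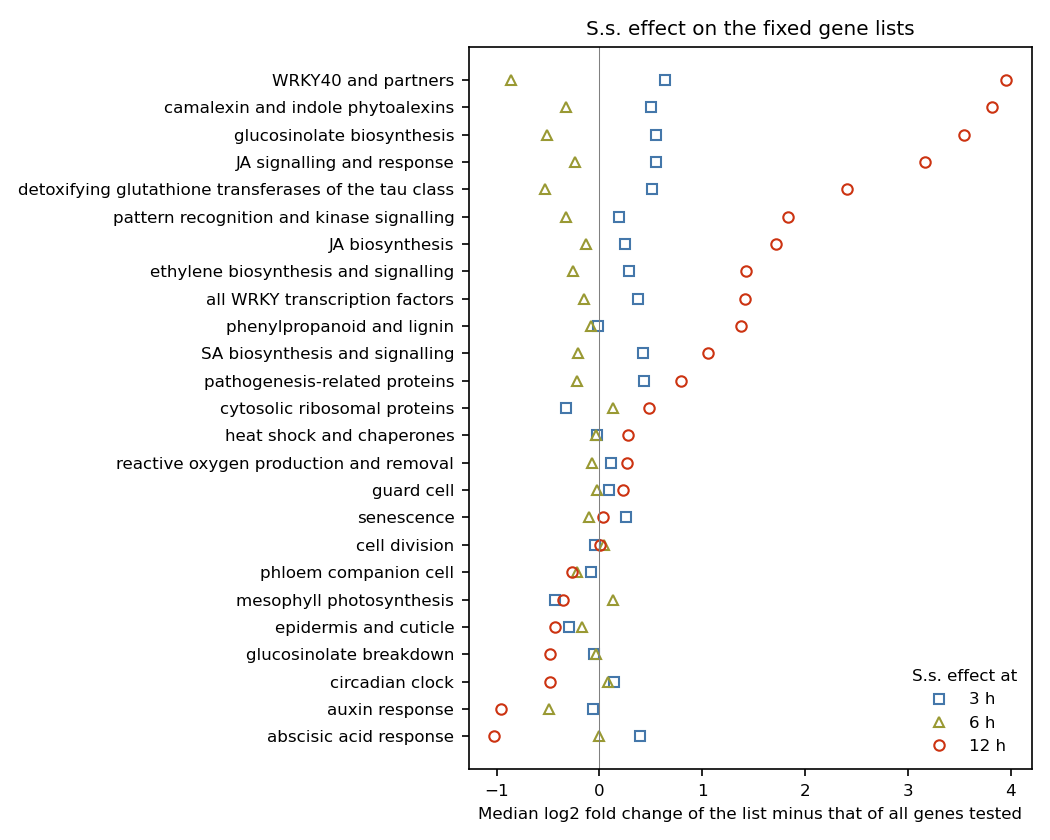
Median log2 fold change with S.s. of each of the 25 gene lists minus that of all genes tested, with a square for 3 h, a triangle for 6 h and a circle for 12 h. At 12 h WRKY40 and its partners lie at 3.96 and the abscisic acid response at -1.02. At 6 h WRKY40 and its partners lie at -0.86, a median of -0.29 without S.s. replicate 1.

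Of 66 photosynthesis genes 37 fell and 0 rose in TPM (median -0.35, and -0.20 and -0.58 without S.s. replicate 1 or 2, adjusted p = 0.535 with an estimated correlation), and 10 fell with median-ratio scaling. LHCA2 (BnaCnng21010D) went from 812 ± 26.2 to 342 ± 127 TPM, a call lost with the libraries without S.s. averaged (limma adjusted p = 0.0892). The phloem companion cell list fell in 12 of 22 cases and rose in 0 (5 falls with scaling, median -0.27, and -0.41 without S.s. replicate 2, adjusted p = 0.277). Its 2 called members with the smallest limma adjusted p were copies of APA1 (BnaA08g25040D and BnaC08g41720D). Whether the list is particular to companion cells was not tested. The cuticle list fell in 14 of 28 and rose in 1 (8 falls with scaling, median -0.43, adjusted p = 0.24). Its wax gene CER1 (BnaCnng09200D) went from 436 ± 2.04 to 144 ± 1.75 TPM, against 146 to 201 TPM in the 8 libraries of 3 h and 6 h. The clock list fell in 16 of 28 and rose in 1 (10 falls with scaling, median -0.48, adjusted p = 0.24), and LUX (BnaA06g17950D), an evening gene, went from 8.68 ± 0.0212 to 2.08 ± 0.7 TPM. Of 808 ribosomal protein genes 129 rose and 45 fell in TPM, and 389 rose and 16 fell with scaling (median 0.48, adjusted p = 0.264). RPL10C (BnaA07g24130D) rose from 43.9 ± 0.332 TPM to 155 and 130 TPM in the 2 S.s. libraries and RPS3C (BnaC02g28200D) fell from 31.1 ± 12.6 to 3.16 ± 0.516 TPM. Rises and falls were 5 and 6 of 26 for guard cells, 10 and 8 of 39 for senescence, 1 and 5 of 18 for cell division and 10 and 11 of 46 for heat shock, and none of these 4 passed camera. The median and the mean of log2 fold changes differed in sign for guard cells (-0.08 and 0.13), senescence (-0.27 and 0.15), heat shock (-0.03 and 0.07) and reactive oxygen (-0.04 and 0.47), before all genes were subtracted. The cell division list had a median of 0.01 relative to all genes (-0.05 to 0.08 with 1 library left out) and a mean of -0.34.

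Adjusted over the list alone, the 12 h rises and falls were 43 and 5 for jasmonate signalling, 24 and 4 for jasmonate synthesis, 26 and 18 for ethylene, 28 and 3 for tau glutathione transferases, 29 and 7 for phenylpropanoids, 32 and 3 for pattern recognition, 0 and 45 for photosynthesis, 1 and 15 for the cuticle, 1 and 17 for the clock, 106 and 32 for WRKY genes and 58 and 25 for ribosomal proteins, and were the same for the other 14. The camera test passed 19 of 25 lists with the preset correlation and 0 with an estimated one (7 unadjusted). The fry test passed 19 in one direction and 25 in either direction. With the libraries without S.s. averaged, 3698 genes rose and 2306 fell, and rises there were 16 of 20 copies of WRKY40 and partners, 15 of 19 camalexin genes, 28 of 42 glucosinolate synthesis genes, 25 jasmonate signalling genes, 13 jasmonate synthesis genes, 12 ethylene genes, 9 salicylic acid genes, 69 WRKY genes, 16 pattern recognition genes, 23 phenylpropanoid genes, 19 glutathione transferases, 10 reactive oxygen genes and 8 pathogenesis-related genes. Falls there were 7 each for abscisic acid, auxin and ethylene, 3 each for the clock and glucosinolate breakdown, 2 for the cuticle and 1 each for photosynthesis and phloem, and ribosomal proteins gave 2 rises and 6 falls. The 12 h count was 15469 and 15646 genes without replicate 1 or 2 of the libraries without S.s. of 12 h and 15603 without S.s. replicate 1 of 12 h. With an added limit of 1 on the absolute log2 fold change, 6009 rose and 7142 fell.

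Whether the response differed between times was tested by the difference of the fold changes. From 6 h to 12 h it became higher for 6593 genes and lower for 9598 (8510 and 4992 with median-ratio scaling). All 7 WRKY40 copies were among the first, by 7.05 (SE 1.13, limma adjusted p = 0.0022) for BnaAnng23990D, 6.83 (SE 0.86) for MSTRG.5775, 5.14 (SE 0.91) for BnaA07g20110D, 4.80 for BnaC02g26030D and for BnaC06g19560D, 2.57 for BnaC06g40170D and 1.33 (SE 0.38, adjusted p = 0.029) for BnaA07g35260D. The lectin-like gene BnaCnng78710D differed by 9.63 (SE 0.60) and RAB18 (BnaCnng27850D) by -6.40 (SE 0.61). From 3 h to 12 h the fold change became higher for 6506 genes and lower for 11297 (9690 and 6692 with scaling). The pyrophosphatase gene PS2 (BnaC02g21720D) differed by 8.69 (SE 0.70). Its levels were 27.2 ± 1.69 TPM without and 3.3 ± 0.898 with S.s. at 3 h, and 0.61 ± 0.0849 and 116 ± 85.6 at 12 h. Among the lowest differences were those of PP2A1 (BnaA01g34970D, -8.99, SE 0.94) and the carotenoid cleavage gene CCD4 (BnaA01g09900D, -8.68, SE 1.19), both on A01. From 3 h to 6 h it became higher for 235 genes and lower for 765, with AGL19 (BnaC07g37730D) at 3.81 (SE 0.71, adjusted p = 0.0366) and the A01 genes PP2A1 at -7.19 and PGK1 (BnaA01g30320D) at -6.63.

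With the libraries without S.s. averaged, 1638 genes became higher and 190 lower from 6 h to 12 h, 834 and 373 from 3 h to 12 h and 0 of either from 3 h to 6 h (2812 genes at an unadjusted p under 0.05, against 8897 here), and the calls of the 7 WRKY40 copies between 6 h and 12 h were lost (adjusted p 0.0602 to 0.275), as were those of PP2A1, PGK1, AGL19 and CCD4. Leaving out 1 library took the 6 h to 12 h count to 10432 (without replicate 1 of 6 h, no S.s.) and to 10284 and 10467 (replicate 1 or 2 of 12 h, no S.s.), and ended the call of BnaA07g35260D without either library without S.s. of 6 h or 12 h or S.s. replicate 1 of 6 h or 12 h (0.0708 to 0.0961). The 3 h to 6 h count of 1000 became 119 and 134 without replicate 1 or 2 of 3 h without S.s., 121 and 123 without those of 6 h, 333 and 332 without those of 12 h, 418 and 517 without S.s. replicate 1 or 2 of 6 h, 2819 without S.s. replicate 2 of 3 h and 1995 and 1993 without S.s. replicate 1 or 2 of 12 h, and it was 429 without the genes of A01 and C01. PP2A1 lost that call without either library without S.s. of 3 h or 6 h, and AGL19 without any library without S.s., without either S.s. library of 6 h, without the genes of A01 and C01 (0.0512), with no filter on low values (0.0699) and with a pseudocount of 0.1 (0.112).

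As background, the libraries without S.s. changed with time. From 3 h to 6 h 2780 genes rose and 3629 fell (3363 and 2698 with median-ratio scaling), from 6 h to 12 h 1814 rose and 1223 fell, and from 3 h to 12 h 7551 rose and 8175 fell. Cytosolic ribosomal proteins fell in 419 and rose in 12 of 808 cases from 3 h to 6 h (adjusted p = 0.116 with an estimated correlation), phenylpropanoid genes rose in 20 of 49 (0.116 as adjusted p) and WRKY40 and its partners in 8 of 20 (adjusted p = 0.257), with 0 falls in both. From 6 h to 12 h the abscisic acid response rose in 12 of 24 cases and fell in 0 (adjusted p = 0.28), and the clock list rose in 12 of 28 and fell in 3 (adjusted p = 0.28). The 3 h to 6 h change includes the low A01 and high C01 level at 3 h. These counts fell to 14, 0 (2847 unadjusted, against 12149) and 39 with the libraries without S.s. averaged. Without replicate 1 or 2 they were 1094 and 1105 (3 h) or 1334 and 1162 (6 h) for the first step. For the second they were 1570 and 1566 (3 h), 294 and 354 (6 h) or 260 and 259 (12 h) without a library without S.s., and 5265 and 5254 (3 h) or 4563 and 4575 (12 h) without an S.s. library. For the third they were 8167 and 7875 (3 h) or 8015 and 8269 (12 h).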

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

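The tests of a rise of A01 genes with S.s., chromosome copies, shared reads, plant of origin, depth, distance along the response, technical copies and the share of the highest genes were chosen after the results were seen, and those of TPM scaling and transcript length before. The test of distance was narrowed to genes outside the shifted chromosomes after its value over all genes (0.35) was seen.

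The effect of S.s. differed between times by the test of the difference itself for 1000 genes between 3 h and 6 h, 16191 between 6 h and 12 h and 17803 between 3 h and 12 h. Between 6 h and 12 h the difference on the log2 scale was 5.14 for WRKY40 copy BnaA07g20110D, 1.33 for BnaA07g35260D, 7.05 for BnaAnng23990D, 4.80 for BnaC02g26030D, 4.80 for BnaC06g19560D, 2.57 for BnaC06g40170D and 6.83 for MSTRG.5775. In the same comparison it was 9.63 for the lectin-like gene BnaCnng78710D and -6.40 for RAB18 (BnaCnng27850D). Between 3 h and 6 h it was -7.19 for PP2A1 (BnaA01g34970D), -6.63 for PGK1 (BnaA01g30320D) and 3.81 for AGL19 (BnaC07g37730D). Between 3 h and 12 h it was 8.69 for PS2 (BnaC02g21720D), -8.99 for PP2A1 and -8.68 for CCD4 (BnaA01g09900D).

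Genes of A01 stood low and those of C01 high in both libraries without S.s. of 3 h. PP2A1, PGK1 and CCD4, among the largest differences, are A01 genes. The 12 h levels also enter the differences between 3 h and 12 h. At 12 h CCD4 had 184 and 184 TPM without S.s. and 3.06 and 27.7 with S.s. PP2A1 had 322 and 335 TPM without S.s. and 27.5 and 148 with S.s. at that time. Both A01 medians lay at least 0.56 below those of all other 10 libraries, which include the other 4 without S.s. This argues against a rise of A01 genes caused by S.s. only as far as 6 h and 12 h show their level without S.s. No other library without S.s. of 3 h was at hand, so a low level particular to that time is not excluded. Reads divided differently between A01 and C01 copies and, as a hypothesis, plants with fewer copies of A01 segments and more of C01 cannot be told apart, since no DNA was measured and the values at hand describe the pattern itself. These are a share of A01 genes under 0.1 times their median that was 28.4 percentage points higher there than in the S.s. libraries of 3 h, and C01 medians of 0.30 and above. Windows of A01 also reached -0.77 in S.s. replicate 2 of 3 h and -0.9 in S.s. replicate 1 of 12 h, A10 medians stood at 0.20 and 0.21 in the same 2 libraries without S.s., and the S.s. effect at 3 h on A01, C01 and A10 cannot be separated from these shifts.

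The 2 libraries without S.s. of each time lay far closer together than the 2 S.s. libraries, and a lower depth of the latter is argued against by a ratio of estimated reads of 1.03. Separate plants, a shared plant or pool and technical copies of 1 RNA cannot be told apart for the pairs without S.s. Their largest difference over windows of 100 genes, at most 0.17 (log2), is the closeness itself, and their spread was up to 1.94 times the estimated counting noise at 100 to 1000 TPM and 3.27 times over 1000 TPM, an estimate that leaves out library preparation. Different distances of the S.s. libraries of 12 h along the response also stay open, since the r of 0.33 across genes between their difference and their effect comes from the same 2 libraries. If the pairs without S.s. share a plant or an RNA, the p-values are too small. The fit with these libraries averaged takes its spread from the S.s. pairs alone. Its counts would be the ones to read only if the 2 S.s. libraries of a time came from separate plants, which the labels do not say.

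At 12 h 65.9% of the called genes fell in TPM. A few abundant genes taking a larger share of the S.s. libraries are argued against, since the 10 highest genes held at least 1.94 percentage points less there, and a loss of long transcripts is argued against by a difference of -0.02 between the medians of the longest and the shortest genes, 1 of 4 length classes each. The scaling of TPM stays open, because 42.7% fell with median-ratio scaling, and without a count of RNA per cell neither scaling is known to be right. A biological excess of falling genes with S.s. is the other open explanation and was not tested.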

How the results depend on the processing

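Averaging the libraries without S.s., the separate spread, the omission of chromosomes and median-ratio scaling of the lists were chosen after the data were seen. The planned DESeq2 and limma-voom fits were not run, since they need counts, and median-ratio scaling stood in for another count normalization. The cause of each change below was not tested, except that fits with fewer libraries or genes have less to test. With the libraries without S.s. averaged, the counts of changed genes were 0 at 3 h (4815 at an unadjusted limma p under 0.05), 0 at 6 h (942) and 6004 at 12 h. The differences of effects gave 0 between 3 h and 6 h (2812), 1828 between 6 h and 12 h and 1207 between 3 h and 12 h, and the times without S.s. gave 14, 0 (2847) and 39 in the same order. With only the 4 libraries of that time, limma called 0 at 3 h (10210 unadjusted), 0 at 6 h (4924) and 17031 at 12 h. Without genes of A01 and C01, 2548 passed at 3 h and 429 between 3 h and 6 h, and without all shifted chromosomes 2290, 376 and, without S.s. between 3 h and 6 h, 3749. An absolute log2 fold change of at least 1 left 2484 at 3 h, 13151 at 12 h and 3590, 1715 and 8537 for the times without S.s. With no filter on low values 30 passed at 6 h and 622 between 3 h and 6 h, and with a pseudocount of 0.1 1556 did in the latter. A separate spread for S.s. libraries gave 17563, 14127 and 25659 for the times without S.s. Median-ratio scaling gave 11410 rises and 8510 falls at 12 h (8048 and 15575 in TPM). Of the lists, camera with an estimated correlation passed 0 at 3 h, 0 at 6 h and 0 at 12 h (1, 3 and 7 unadjusted). Fry in one direction passed 5 at 3 h, 1 at 6 h and 19 at 12 h, and fry in either direction 24, 7 and 25.

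Leaving out 1 library at a time, which assumes that the lone library left in a group varies like the other groups, gave 499 to 5684 genes at 3 h, 4 to 57 at 6 h and 15469 to 25855 at 12 h. The differences of effects ranged from 119 to 2819 (3 h and 6 h), 10284 to 19448 (6 h and 12 h) and 12218 to 19785 (3 h and 12 h), the times without S.s. from 1094 to 8706, 259 to 5265 and 7875 to 18116, and the lists from 6 to 17 at 3 h, 10 to 18 at 6 h and 19 to 20 at 12 h. The replicate numbers did not pair the libraries (r between -0.033 and 0.053 across groups). With them as a replicate block, 3648 genes passed at 3 h, 3 at 6 h and 23245 at 12 h, 729, 15695 and 17288 in the differences and 5736, 2552 and 15160 without S.s., and 13, 17 and 20 lists.

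Of 151 results of named genes, 14 changed direction when 1 library was left out, 0 of them called ones. At 3 h, log2 fold changes without S.s. replicate 1 and 2 of that time were -0.21 and 0.50 for BnaA07g35260D, -0.23 and 0.51 for BnaC06g40170D, -0.13 and 0.20 for BnaC01g06660D (-0.11 without replicate 1 of those without S.s.), -0.10 and 1.14 for BnaC07g43490D, -0.03 and 1.47 for MSTRG.23140, -0.07 and 0.72 for BnaC04g06800D and -0.10 and 0.37 for BnaC07g27590D. At 6 h they were 0.20 and -2.01 for BnaA07g20110D, 0.14 and -2.96 for BnaAnng23990D, 0 and -1.57 for BnaC02g26030D, 0.24 and -1.55 for BnaC06g19560D, 0.11 and -1.38 for BnaC06g40170D, 0.26 and -0.18 for BnaC07g27590D and -0.16 and 0.30 for BnaC03g45470D. With the libraries without S.s. averaged 95 of the 151 stayed on their side of the threshold and 56 lost their call, with only the 4 libraries of a time 99 and 37 of 136, without genes of A01 and C01 129 and 2 of 131, with the block 146 and 5 (adjusted p 0.0626 for BnaA07g35260D at 12 h and, at 6 h, 0.0514 for NSP5 and 0.0731 for IGMT1, BnaC05g14380D and MSTRG.49958), with no filter or a pseudocount of 0.1 148 and 3 each, and with median-ratio scaling or a separate spread 150 and 1 each. Leaving out a library without S.s. of 3 h ended 21 or 19 calls, of 6 h 11 each and of 12 h 8 or 9, and leaving out an S.s. library ended 1 to 9. TPM keeps no depth, so what depth limits was not tested. The simulated test at 12 h called 11 of 100 genes with a log2 fold change of 1 and 81 of 100 with 2. Far fewer genes changed there than in the data, so these shares do not describe the 12 h test of the data.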

Other observations

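The tests of spread, of depth and of chance deviations of the shared libraries were chosen after the results were seen, and those of different departures, of A01 and C01, of clock time, of subgenomes and of assembled loci before. The bound of the test of chance deviations was changed after its first value, an r of 0.20, was seen, and the wording of the TPM scaling test was shortened after its value was seen, with its bounds kept.

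Genes that rose at 3 h and those that moved at 12 h came from comparisons of different libraries that share 1 estimate of the spread, so the counts for independent lists, in parentheses, are not those expected with no relation. Of the 2606 genes that rose at 3 h, 522 rose at 12 h (401.1) and 1118 fell (776.3). Of the 1512 that fell at 3 h, 239 rose (232.7) and 425 fell (450.4). Without S.s., between 3 h and 12 h, the abscisic acid response rose in 19 of 24 cases and fell in 0 (adjusted p = 0.222 with an estimated correlation), salicylic acid genes rose in 24 of 49 and fell in 2 (0.282 as adjusted p of the same test), and ribosomal proteins fell in 540 of 808 and rose in 17 (adjusted p = 0.138). Only 39 genes were called between these times with the libraries without S.s. averaged.

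Copies below the limit on expression were not tested. MSTRG.61631, matched to WRKY33, was listed at 5.62 and 2.82 TPM in the 2 S.s. libraries of 12 h and at 0 in all 6 libraries without S.s. The WRKY18 copies BnaC04g12070D and BnaC09g05770D reached 2 and 2.38 TPM at most.

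Few genes passed at 6 h. The estimated depth of the 2 S.s. libraries was 1.1 times that of 3 h, which argues against a lower depth. The spread between them was 0.64 times that of 3 h. This value decides nothing, because the fit shares 1 estimate of the spread per gene over all times. A spread particular to 6 h could therefore not set this count apart from the others. The departures of the 2 S.s. libraries, each from another library without S.s., correlated across genes with an r of 0.13 at 6 h, 0.42 at 3 h and 0.83 at 12 h. A small effect alone would also give a low r, so different departures of the 2 libraries cannot be told apart from a small effect.

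The effect of S.s. at 3 h resembled the change from 3 h to 6 h without S.s. (r = 0.65 across genes), although the comparisons share the 3 h libraries without S.s. With no effect, 100 simulations gave a mean r of 0.37 and a highest of 0.39, and the covariance was 0.326 against 0.053 from the spread of the shared libraries. Without A01 and C01, r was 0.55 (simulated mean 0.37, highest 0.39) and the covariance 0.221 against 0.054, so the likeness did not rest on them alone. The simulated values are too low if the pairs without S.s. share a plant, and the r of at least 0.13 with the change from 6 h to 12 h, which shares none of the 3 h libraries, then leaves chance deviations open. A difference in clock time also stays open, with a median ratio of the 2 changes of 0.30 over 6 clock copies.

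The odds of rising at 12 h were the same for genes of the C and the A subgenome (odds ratio 1, 95% interval 0.95 to 1.05), and those of falling were 1.08 (1.03 to 1.12). Loci assembled outside the named gene models rose less often than named ones (odds ratio 0.48, 0.44 to 0.53), with falls of 27.8% against 29.2% (A) and 30.8% (C). Their median level was also lower, 2.99 TPM against 6.22 and 6.55, and the classes were not matched for it. Genes are not independent replicates, so these intervals cover counting only.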
